A study of Homo sapiens with 6 samples.

How the data were processed

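Ribosome profiling had been carried out in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Cells had received the vehicle DMSO, an inhibitor of the arginine methyltransferase PRMT1 or an inhibitor of PRMT4, which is also known as CARM1. The labels name no compound, dose or time. Each of the 3 treatments had 1 input library, taken as the RNA level, and 1 library of ribosome-protected fragments, called footprints here, which gave 6 libraries in all. Per the labels' protocols, lysates were digested with RNase I, monosomes were collected from sucrose gradients, and footprint libraries followed a small RNA library procedure. The labels describe every library, the inputs included, as ribosome-protected RNA, so how the input RNA was prepared is not given in the sources used here.

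The deposited table held TPM, the length-scaled share of transcripts, as computed by the authors, with 1 column per library, printed to 2 decimals. The submitters' processing notes name cutadapt 1.18, Bowtie 1.1.2, STAR 2.4.2a, RSEM 1.2.22 and the genome build GRCh37.p13, without saying which step each performed. Because TPM divides by gene length and by the library total, it keeps no sequencing depth, so the depth of each library is unknown and no counting interval or count-based test was possible. TPM is also a share of a fixed total: a rise of a few abundant small RNAs lowers every other gene. The column names abbreviate the treatments, and each was assigned to the one library whose label it matched. No column was left without a library.

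The table listed 60461 gene identifiers. The 41 copies from the Y pseudoautosomal region were at 0 TPM in every library and were dropped, which left 60420. Gene symbols were found for 55725 identifiers, and gene types for 56157 in GENCODE release 29. That release is built on a later genome than the authors' build, so it served only for names, gene types, and the GC content and length of each gene's longest transcript, and no coordinates are given.

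Ratios were computed as log2((TPM + 1) / (TPM + 1)) with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The pseudocount of 1 understates the change of genes with low values. Genes with a mean TPM of at least 5 over the 6 libraries were compared, 9040 in all, of which 8117 were protein-coding and 923 were not. Translation efficiency was the footprint value over the input value of the same label. It was computed for all tested genes, but for RNAs that code for no protein it does not measure translation. Each ratio was centred on its median over the tested genes. Before centring, the median was -0.16 for the input labelled PRMT1 inhibitor, -0.37 for the input labelled PRMT4 inhibitor, -0.15 and -0.01 for the corresponding footprints, and 0.02 and 0.37 for translation efficiency. Every ratio given here is relative to the median tested gene unless stated otherwise.

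With 1 library per group there is no replicate error, so no p-value was computed, and every difference describes these libraries and not the treatments in general. An interaction model for translation efficiency would have had no residual degrees of freedom. Genes at least 2-fold higher or lower were counted. Before the data were examined, 39 gene lists had been fixed, and 34 of them had the 5 or more members past the filter that were required. For each list the median ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stands apart, in the sense used here, below percentile 2.5 or above percentile 97.5 of those random lists. Members of a list can vary together, which genes drawn at random do not reproduce. The random lists can then spread too little, so these bounds are not an error rate.

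Genes were named by size alone, by a rule also fixed beforehand. Candidates were the 3606 protein-coding genes with a mean TPM of at least 20. The rule took the 4 highest and 4 lowest in input, the 5 highest and 5 lowest in footprints and the 6 highest and 6 lowest in translation efficiency for each inhibitor, and the 4 highest and 4 lowest in translation efficiency between the inhibitors. It also took up to 2 members highest and 2 lowest for each list described, and PRMT1 and CARM1. Genes picked by size are those most exposed to noise. Other genes named were chosen after their values were seen, and the text says so.

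Both inhibitors were compared with the same DMSO libraries, which alone gives their ratios a positive correlation. Its size was estimated from 100 simulations of unchanged libraries with equal independent noise, drawn from the differences between the inhibitor libraries. With equal noise the simulated correlation comes to 0.50 for any data, so that value belongs to the assumption and not to these libraries. Those differences include any real ones, which raises the simulated covariance. They hold no information on the DMSO libraries, and a noisier DMSO library would make the true covariance larger than the simulated one. For shared genes, as many simulated genes were called in each direction as had been observed for each inhibitor, a rule added after seeing the data. The noise was shuffled over genes, so every simulated gene had the same spread. Where some genes are noisier than others, more sharing would arise than the simulation gives.

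The computation was tested on simulated libraries. Of 195 genes given a 4-fold change in translation efficiency, 97.4% were recovered at the 2-fold threshold among 8910 genes tested, 77 of the others were called, and 2 of 40 random lists stood apart. The correlation between assays of the ratio of the inhibitors was 0.42 with labels in place and -0.40 with the labels of an assay crossed. All these values follow from effect sizes and a noise level chosen for the simulation, the noise being alike for every gene. They check the computation, and give neither an error rate nor an expected correlation for the real libraries.

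Alternatives fixed beforehand were pseudocounts of 0.1 and 5, minimum mean TPM of 1 or 20 or none, no centring, no centring after rescaling without small and mitochondrial RNA, centring on a lowess trend, protein-coding genes alone, Spearman correlation, and random lists matched on translation efficiency too. Chosen after seeing the data were an adjustment of each ratio for GC content and transcript length, a restriction of the lists to protein-coding genes, and translation efficiency with the input library that carries the other inhibitor's label. GC content was known for 8958 of the tested genes.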

Results

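Ribosome profiling was used to compare RNA levels and ribosome footprints in HEK293T cells under DMSO, a PRMT1 inhibitor and a PRMT4 inhibitor. PRMT1 and PRMT4 (CARM1) are type I arginine methyltransferases, which place asymmetric dimethyl marks on RNA-binding proteins, histones and coactivators. Each treatment was represented by 1 input and 1 footprint library, so there were no replicates and no difference below has a replicate check. Between 30576 and 30860 genes had a value above 0 in the input libraries, and between 20485 and 21161 in the footprint libraries. Because the footprint library of each inhibitor followed the input library of the other inhibitor more closely than that of its own label (values given further on), libraries are named by their labels throughout.

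The messages of the targeted enzymes were measured in every library. PRMT1 (ENSG00000126457.21_3) stood at 136 TPM in the DMSO input, 90.7 TPM in the input labelled PRMT1 inhibitor and 86.1 TPM in the input labelled PRMT4 inhibitor, and at 276, 190 and 207 TPM in the corresponding footprints. CARM1 (ENSG00000142453.11_3) stood at 32.0, 22.8 and 23.6 TPM in input and at 99.9, 63.4 and 81.1 TPM in footprints. Both messages were therefore lower than in DMSO in all 4 inhibitor libraries, with centred log2 ratios from -0.42 to -0.29 for PRMT1 and from -0.50 to -0.06 for CARM1. An inhibitor acts on the enzyme and not on its message, so these levels do not check the labels.

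The make-up of the libraries differed with treatment. Protein-coding genes held 45.7% of TPM in the DMSO input, 38.7% in the input labelled PRMT1 inhibitor and 33.4% in the input labelled PRMT4 inhibitor. The 7SK RNA, RN7SK, a nuclear RNA that restrains transcription elongation, stood at 15769 TPM in the DMSO input, 52493 TPM in the input labelled PRMT1 inhibitor and 81934 TPM in the input labelled PRMT4 inhibitor, and was listed at 0 in every footprint library. In footprints, protein-coding genes held 74.3% in DMSO, 62.3% under the PRMT1 inhibitor label and 70.6% under the PRMT4 inhibitor label. Small nucleolar RNAs, which guide the modification of ribosomal RNA, held 0.81% of the DMSO footprint library, 3.79% of that labelled PRMT1 inhibitor and 1.03% of that labelled PRMT4 inhibitor. Mitochondrially encoded messages together held only 0.042%, 0.029% and 0.023% of TPM in the inputs of DMSO, the PRMT1 label and the PRMT4 label. In the corresponding footprints they held 0.010%, 0.011% and 0.006%, so every ratio of this group rests on a small residue.

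In the input library labelled PRMT1 inhibitor, the message of HMOX1 (ENSG00000100292.16_2), the stress-inducible heme oxygenase that degrades heme, was higher than in DMSO, at 21.6 against 7.53 TPM (log2 ratio 1.57). The ferritin light chain FTL (ENSG00000087086.14_3), an iron storage protein, was at 556 against 336 TPM (0.88), galectin LGALS1 had a ratio of 0.57 and the cilium-associated DZIP1 one of 0.56. At the low end were TSC22D3, a glucocorticoid-inducible leucine zipper protein, at 33.1 against 80.6 TPM (-1.10), and DDIT4, a stress-induced inhibitor of mTORC1, at 17.0 against 39.0 TPM (-0.99). Loci without a symbol, ENSG00000255339 at -1.89 and ENSG00000274276 at -0.84, were also named by size, but their reads can be shared with overlapping genes or near-identical copies and their values are uncertain.

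By group, glycolysis genes stood lower in this input library: all 18 measured members had ratios below 0 (median -0.36), with LDHA, lactate dehydrogenase A, at -0.57 and PGK1, phosphoglycerate kinase, at -0.52. Aminoacyl-tRNA synthetases, which charge transfer RNAs, were below 0 in 19 of 20 members (median -0.24), with GARS1 at -0.71 and YARS1 at -0.62. Replication-dependent histones were below 0 in 37 of 42 (-0.28), although histone genes share reads between copies. Integrated stress response genes, the ATF4 programme of amino acid supply and stress adaptation, were below 0 in 16 of 22 (-0.22), with DDIT4 at -0.99 and the serine synthesis enzyme PHGDH at -0.77. Mitochondrially encoded messages were below 0 in 9 of 10 (-0.43), with MT-ND4L at -0.81 and MT-CYB at -0.74. Where a call was lost under some of the alternatives run for it, the number that kept it is given in brackets. Cytoskeleton genes had a median of -0.22, hnRNP proteins, which bind nuclear pre-mRNA, -0.19 (7 of 8), mitochondrial ribosomal proteins -0.15, nuclear oxidative phosphorylation subunits -0.15 (5 of 8), ribosome biogenesis factors -0.13 and cholesterol synthesis genes -0.12, and all of these stood apart below their matched random lists. KRAB zinc finger genes, a family of transcriptional repressors, were above 0 in 34 of 36 (0.32), with ZNF85 at 0.63 and ZNF91 at 0.53. ER chaperones were above 0 in 15 of 19 (0.19), with PDIA6 at 0.51 and DNAJB11 at 0.48. Nuclear non-coding RNAs (0.28), small structured RNAs (0.41) and snoRNA host RNAs (0.10, kept in 7 of 8, and -0.06 without centring) also stood apart above.

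In counts, 56 genes were at least 2-fold higher and 18 at least 2-fold lower. Of these, 71 were not protein-coding. The 3 protein-coding ones were HMOX1, TSC22D3 and ENSG00000255339. The share of higher genes among those past 2-fold was 75.7%, against 65.1% without centring, 50.0% after rescaling without small and mitochondrial RNA, 63.6% after adjustment for GC content and length and 60.2% with no filter. Without centring every list median of this library was lower by 0.16. Of the calls above, the lowess trend left mitochondrial ribosomal proteins at -0.07, oxidative phosphorylation subunits at -0.05, histones at -0.16 and hnRNP proteins at -0.09. Adjustment for GC content and length left integrated stress response genes at -0.15, cholesterol synthesis genes at -0.05, nuclear non-coding RNAs at 0.16 and snoRNA host RNAs at 0.06, and rescaling put ER chaperones at 0.12, snoRNA host RNAs at 0.03, and cholesterol synthesis genes and ribosome biogenesis factors at -0.19 and -0.19.

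HMOX1 was again the highest named gene in the input library labelled PRMT4 inhibitor, at 157 TPM against 7.53 TPM in DMSO (log2 ratio 4.57). CDKN1A, the p53-induced cyclin-dependent kinase inhibitor p21, was at 22 against 12.9 TPM (1.1). The lowest candidates with a symbol were AL035425.2 (-2.35), a clone-named locus of uncertain value, CA2 (ENSG00000104267.9_2), carbonic anhydrase 2, at 97.1 against 350 TPM (-1.48), and the linker histone H1-3 at 72.4 against 243 TPM (-1.37). Loci without a symbol among the extremes were ENSG00000144785 at 2.60, with under 7 TPM in every input library, ENSG00000272772 at 1.82 and ENSG00000267261 at -1.44, all with values that can rest on shared reads.

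Integrated stress response genes stood higher in this library, above 0 in 20 of 22 members (median 0.40, but 0.03 without centring and 0.12 after rescaling), with the amino acid transporter subunit SLC3A2 at 0.95 and the transcription factor DDIT3 at 0.91. Genes induced by p53 were above 0 in 17 of 20 (0.47, but 0.11 and 0.20 on those scales), 3 of them at least 2-fold: PHLDA3 at 1.16, CDKN1A at 1.1 and the growth arrest gene GADD45A at 1.1. HEK293T cells carry large T antigen, which binds p53. Lower groups were ribosome biogenesis factors, below 0 in 42 of 45 (-0.32), with WDR12 at -0.63 and LTV1 at -0.61, DNA replication genes, below 0 in 41 of 46 (-0.24), with the helicase subunits MCM7 at -0.71 and MCM6 at -0.64, and hnRNP proteins, below 0 in 19 of 24 (-0.38), with HNRNPK at -0.79 and HNRNPC at -0.73. Mitochondrially encoded messages were below 0 in all 10 (-0.51), mitochondrial ribosomal proteins in 65 of 74 (-0.28) and nuclear oxidative phosphorylation subunits in 66 of 75 (-0.27). Glycolysis genes had a median of -0.22 that did not stand apart (percentile 4.09), with LDHA at -1.16 and PGK1 at -0.95. ER chaperones had a median of 0.16 that did not stand apart and lay at -0.21 without centring and -0.11 after rescaling. Nuclear non-coding RNAs stood apart above at 0.35 (5 of 6), a median that lay at -0.01 without centring. Also above were snoRNA host RNAs at 0.10 (7 of 8), which lay at -0.27 without centring and -0.18 after rescaling, and small structured RNAs at 0.47, which lay at 0.12 after adjustment for GC content and length. In the last group RN7SK had a ratio of 2.74, while RNU6-1, a copy of the U6 spliceosomal RNA, went from 287 TPM to a listed 0.

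At 2-fold, 179 genes were higher and 42 lower, of which 25 and 12 were protein-coding. Small nucleolar RNA genes made up 74 of those higher. The share of higher genes was 81.0% with centring, 27.1% without it, 19.7% after rescaling and 67.4% after adjustment for GC content and length. With no filter on low values it was 44.8% (190 against 234). That setting also moved the centre, which was then the median of all genes admitted. It held fewer higher genes than the 263 at a mean TPM of at least 1, although more genes were tested. The balance of directions therefore depended on the scale. Without centring every list median was lower by 0.37. Rescaling put hnRNP proteins at -0.65, ribosome biogenesis factors at -0.60, mitochondrial ribosomal proteins at -0.57, oxidative phosphorylation subunits at -0.54, DNA replication genes at -0.52 and nuclear non-coding RNAs at 0.07. The lowess trend put hnRNP proteins at -0.20, mitochondrial ribosomal proteins at -0.19, oxidative phosphorylation subunits at -0.09 and snoRNA host RNAs at 0.17.

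In footprints labelled PRMT1 inhibitor, HMOX1 had the highest ratio among candidates, with 642 TPM against 33.0 TPM in DMSO (log2 ratio 4.39). It was followed by genes of the secretory pathway and others: the ER chaperone calnexin, CANX, at 52.4 against 22.7 TPM (1.32), the oligosaccharyltransferase subunit DDOST at 40 against 17.8 TPM (1.28), the ring finger gene UNKL (1.26) and the ER prolyl isomerase FKBP10 at 14.4 against 6.50 TPM (1.2). The lowest were CA2 at 195 against 620 TPM (-1.52), the actin-bundling protein FSCN1 at 17.9 against 49.4 TPM (-1.27), the junction scaffold AMOT at 12 against 32.7 TPM (-1.22), the scaffold NHERF2 (-1.20) and the nucleotide precursor enzyme PRPS2 (-1.14).

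**Figure D1:**
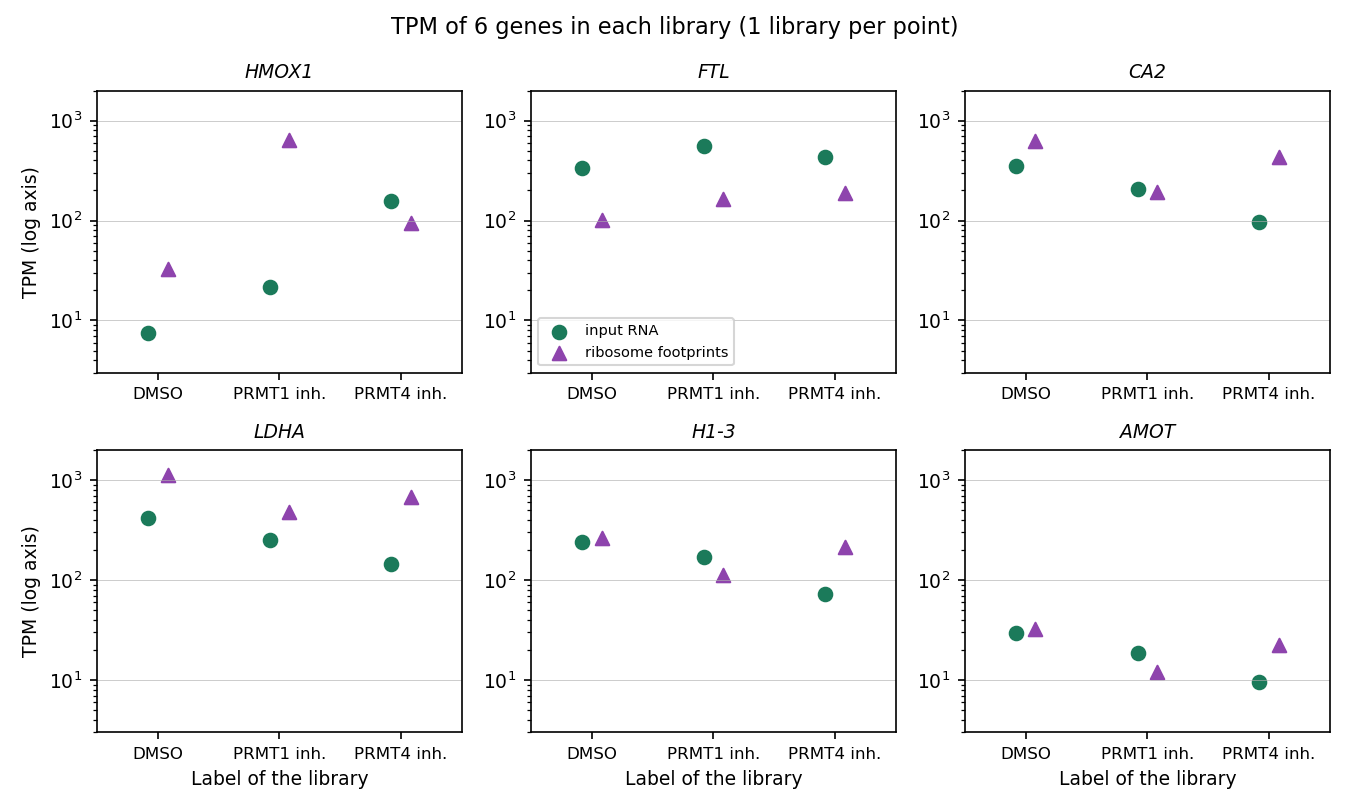
TPM on a log axis for HMOX1, FTL, CA2, LDHA, H1-3 and AMOT, with 1 point per library, circles for input RNA and triangles for ribosome footprints, arranged by the treatment on the label. HMOX1 was at 157 TPM in the input labelled PRMT4 inhibitor and at 642 TPM in the footprints labelled PRMT1 inhibitor, while CA2 was lowest, at 97.1 and 195 TPM, in those same libraries of each assay.

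Glycolysis genes had the lowest group median in these footprints, at -0.57, and all 18 members were below 0, with LDHA (ENSG00000134333.13_3) at 485 against 1117 TPM (-1.06) and the aldolase ALDOC at -0.93. Ribosome biogenesis factors were below 0 in 42 of 45 (-0.39), with MYBBP1A at -0.78 and UTP18 at -0.73, hnRNP proteins in 21 of 24 (-0.37), with HNRNPL at -0.85 and the splicing repressor PTBP1 at -0.81, and proteins with arginine and glycine-rich RGG motifs, preferred sites of PRMT1, in 23 of 28 (-0.33), with nucleolin, NCL, at -1.0 and SERBP1 at -0.74. DNA replication genes were below 0 in 35 of 46 (-0.26), with UHRF1 at -1.17 and MCM7 at -0.80. Cytoskeleton genes (-0.36), replication-dependent histones (-0.32), known CARM1 substrates (-0.27, kept in 6 of 8), heat shock proteins (-0.25, kept in only 3 of 8) and mitochondrial ribosomal proteins (-0.21) stood apart below as well. On the other side, p53-induced genes were above 0 in 16 of 20 (0.37), with PHLDA3 at 1.1 and CDKN1A at 1.07, ER chaperones in 16 of 19 (0.33), with CANX at 1.32 and P4HB at 0.90, KRAB zinc finger genes in 30 of 36 (0.26, kept in 6 of 7), with ZNF780A at 1.04, and integrated stress response genes in 19 of 22 (0.24, kept in 7 of 8), with DDIT3 at 1.37 and SLC3A2 at 0.87. Nuclear non-coding RNAs were above 0 in all 7 (0.48, kept in 5 of 6), with MALAT1 at 204 against 51.4 TPM (2.11), and snoRNA host RNAs in 16 of 24 (0.20, kept in 7 of 8), with SNHG5 at 1.46 and GAS5 at 1.07. Small structured RNAs had a median of 0.47, which lay at -0.21 after adjustment for GC content and length.

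In total 294 genes were at least 2-fold higher and 52 lower, of which 92 and 23 were protein-coding. Among 156 small nucleolar RNA genes, 121 were at least 2-fold higher, with a median log2 ratio of 2.04. Of all genes past 2-fold, 85.0% were higher with centring, 70.1% without, 63.7% after rescaling, 65.2% after adjustment for GC content and length and 66.5% with no filter. List medians were lower by 0.15 without centring. With the lowess trend hnRNP proteins lay at -0.23, histones at -0.17, cytoskeleton genes at -0.17, known CARM1 substrates at -0.15, mitochondrial ribosomal proteins at -0.12 and heat shock proteins at -0.11.

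Footprints labelled PRMT4 inhibitor lay closer to DMSO. HMOX1 was at 93.9 against 33.0 TPM (log2 ratio 1.49), LGALS1 at 44.8 against 22.1 TPM (1.0), FTL at 188 against 102 TPM (0.88), ZNF33B had a ratio of 0.87 and the readthrough locus NEDD8-MDP1, which shares reads with its parent genes, one of 0.84. The lowest were CKMT1B (-1.35) and HSPA1B (-1.19), each with a near-identical copy that makes its value uncertain, the mitochondrially encoded MT-CO3 at 2.97 against 8.56 TPM (-1.26), the mitochondrial DNA polymerase POLG at 3.98 against 10.6 TPM (-1.21) and the cystathionine synthase CBS at 6.67 against 16.2 TPM (-1.16).

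Mitochondrially encoded messages had the lowest group median in this library, -0.61, with all 10 below 0 and 2 at least 2-fold lower, MT-CO3 and MT-ATP6 (-1.17). Their footprint values were low in all libraries, 8.56 and 8.37 TPM for this pair in DMSO. Glycolysis genes were below 0 in 17 of 18 (-0.37), with LDHA at -0.72 and PGAM1 at -0.57, aminoacyl-tRNA synthetases in 17 of 20 (-0.26), with YARS1 at -0.84 and VARS1 at -0.65, and integrated stress response genes in 16 of 22 (-0.22), with CBS at -1.16 and DDIT4 at -0.88. The arginine methyltransferase family had a median of -0.21, hnRNP proteins -0.18, known CARM1 substrates -0.16 (5 of 8), with the pyruvate kinase PKM at -0.82 and ARID1A at -0.62, cytoskeleton genes -0.16, cholesterol synthesis genes -0.16, heat shock proteins -0.15 (6 of 8), histones -0.14, RGG-motif proteins -0.13 (6 of 8), mitosis genes -0.11 and ribosome biogenesis factors -0.09 (5 of 8), and all stood apart below. KRAB zinc finger genes were above 0 in all 36 (0.33), with ZNF611 at 0.95 and ZNF780A at 0.90. Nuclear non-coding RNAs (0.21, kept in 4 of 6), selenoproteins (0.16) and targets of the oxidative stress factor NRF2 (0.12, kept in 7 of 8), with HMOX1 at 1.49 and NQO1 at 0.92, stood apart above.

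There were 58 genes at least 2-fold higher and 23 lower, of which 5 and 9 were protein-coding. The 5 were HMOX1 and, named after their values were seen, CCZ1B, TVP23C, ENSG00000248235 and ENSG00000261459, of which the last was listed at 0 in the DMSO footprints. Of all genes past 2-fold, 71.6% were higher with centring, 69.9% without, 54.8% after rescaling, 49.3% after adjustment for GC content and length and 60.4% with no filter. The lowess trend put heat shock proteins at -0.09.

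**Figure D2:**
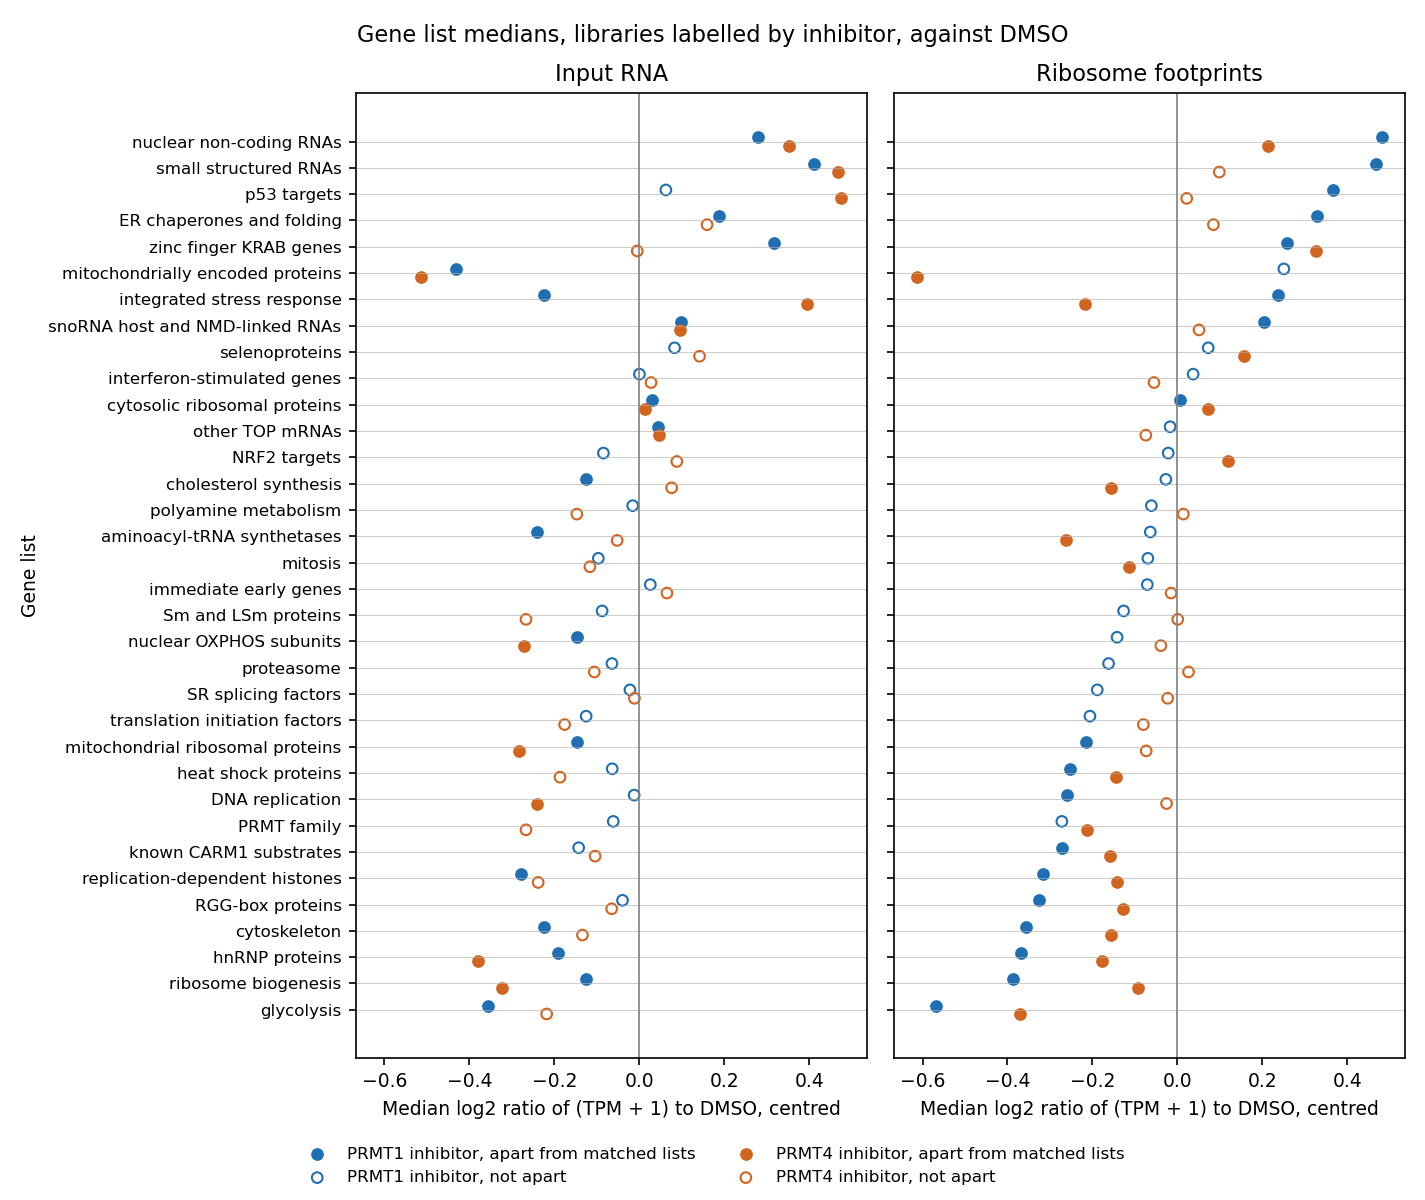
Median centred log2 ratio to DMSO (horizontal axis) of 34 gene lists (vertical axis) in input RNA (left) and ribosome footprints (right), blue for libraries labelled PRMT1 inhibitor and orange for those labelled PRMT4 inhibitor, filled where the median stood apart from matched random lists. Integrated stress response genes were at -0.22 and 0.40 in input and at 0.24 and -0.22 in footprints, and glycolysis genes were below 0 in all 4 libraries.

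Cytosolic ribosomal proteins, whose messages carry 5' terminal oligopyrimidine tracts, had medians of 0.03 and 0.01 in input and 0.01 and 0.07 in footprints for the PRMT1 and PRMT4 inhibitor labels, although each stood apart above its matched lists, which as abundant genes lay lower. Without centring the first 3 of these medians lay at -0.13, -0.35 and -0.14, after rescaling at -0.03, -0.26 and -0.04, and with the lowess trend at 0.14, 0.12 and 0.08. Other messages of this kind had input medians of 0.04 and 0.05, also apart above (-0.12 and -0.32 without centring, -0.02 and -0.23 after rescaling, 0.16 and 0.19 with the lowess trend), and footprint medians of -0.02 and -0.07. Translation initiation factors, SR splicing factors, Sm and LSm proteins, proteasome subunits, interferon-stimulated genes, immediate early genes and polyamine metabolism genes stood apart in neither assay for either inhibitor, which does not show that they stayed level: Sm and LSm proteins had an input median of -0.27 under the PRMT4 inhibitor label and initiation factors a footprint median of -0.21 under the PRMT1 inhibitor label. Extracellular matrix genes and mitochondrial ribosomal RNAs had 4 and 2 members past the filter, too few to compare. Of markers of other cell types, the highest for fibroblasts was COL1A1 at 3.82 TPM and the highest for blood cells HBA1 at 13.3 TPM, both in DMSO footprints. In each footprint library 2 of 12 blood cell markers were at 5 TPM or more. No marker of HeLa-like epithelium reached 0.64 TPM in any library.

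The ratios of the inhibitors to DMSO were compared across genes, which are not independent replicates. In input they had a Pearson correlation of 0.39 over 9040 genes, with a covariance of 0.051. Simulated unchanged libraries that share a control had 0.50, the value that equal noise gives for any data, and a covariance of 0.088. In footprints the correlation was 0.46 against 0.50, with covariances of 0.082 and 0.116. Of the genes at least 2-fold higher, 25 were shared between inhibitors in input (1.11 for independent lists, 26.8 for simulated lists of the same sizes) and 41 in footprints (1.89 and 29.9). Among lower genes, 4 were shared in input (0.084 and 8.68) and 4 in footprints (0.13 and 10.9). There is only 1 DMSO library per assay, so part of any overlap may come from it. Genes also differed in spread, which the simulation does not hold. The standard deviation of footprint ratios was 1.15 and 0.68 for genes not protein-coding, against 0.37 and 0.25 for protein-coding ones (PRMT1 label first). The simulated numbers of shared genes may therefore be too low. HMOX1 and FTL had ratios of at least 0.73 under both labels in both assays.

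Input and footprints were then set against each other over the 8117 protein-coding genes. The footprint ratio labelled PRMT1 inhibitor correlated with the input ratio of the same label at r = 0.36 and with the input ratio labelled PRMT4 inhibitor at r = 0.56. The footprint ratio labelled PRMT4 inhibitor correlated at r = 0.20 with its own input and at r = 0.46 with the other. The ratio of the inhibitor libraries to each other, which does not involve DMSO, correlated between input and footprints at r = -0.42 (Spearman -0.41). Of 238 genes past 0.5 on the log2 scale in both assays, 225 (94.5%) had opposite signs. HMOX1, FKBP10, CA2, H1-3 and RPS26 were among them, the last a ribosomal protein gene with many pseudogene copies.

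**Figure D3:**
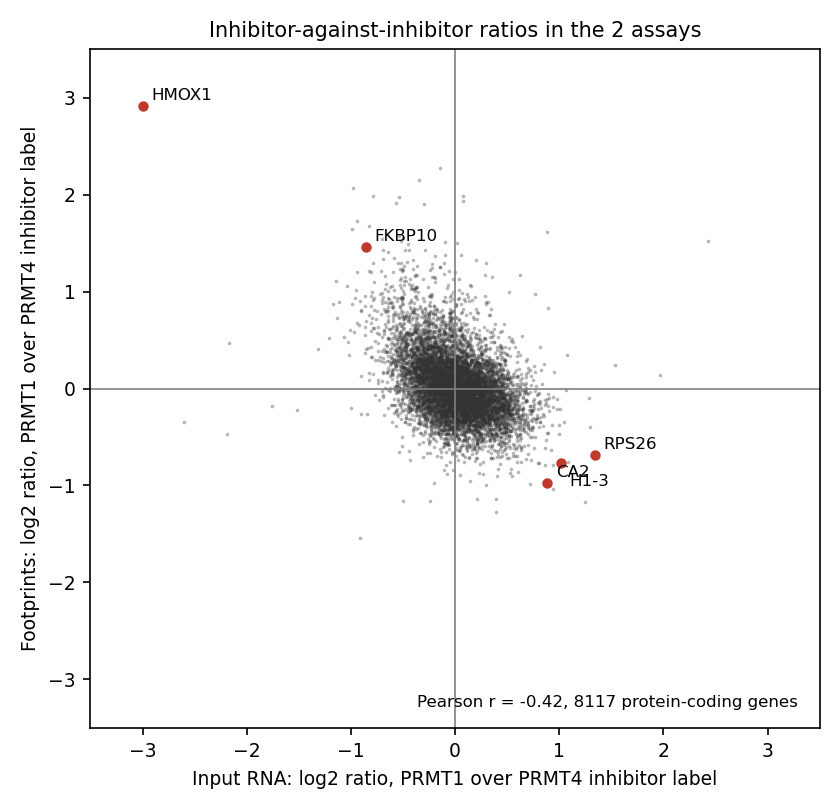
Log2 ratio of the library labelled PRMT1 inhibitor to that labelled PRMT4 inhibitor in input RNA (horizontal axis) and in ribosome footprints (vertical axis), 1 point per protein-coding gene, with 5 genes marked. Over the 8117 genes r was -0.42, and the points run from upper left, with HMOX1, to lower right, with CA2 and RPS26.

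Translation efficiency, the question the design poses, takes its direction from the pairing of labels, so gene values, list medians and counts are followed by those with the input of the other label. For the PRMT1 inhibitor label the highest candidates were HMOX1 (2.82, and -0.20 with the other input), the unnamed ENSG00000255339 (1.99 and -0.20), FKBP10 (1.5 and 0.62), CDK5RAP3 (1.25 and 0.70), PPP1R16A (1.21 and 0.70) and DDOST (1.21 and 0.59). The lowest were RPS26 (-1.28 and 0.04), the histone-binding protein RBBP7 (-1.14 and -0.64), MORC3 (-0.97 and -0.38), the chaperone HSPA4 (-0.94 and -0.44), BCCIP (-0.94 and -0.23) and MIX23 (-0.93 and -0.02). Integrated stress response genes were above 0 in all 22 members (median 0.42), but with the other input 16 of 22 were below 0 (-0.11). Mitochondrially encoded messages were at 0.72 (0.71 with the other input), a median that rests on low footprint values. Genes induced by p53 were at 0.30 (-0.11), ER chaperones at 0.26 (0.08), aminoacyl-tRNA synthetases at 0.20 (0.09) and snoRNA host RNAs at 0.12 (0.20). Ribosome biogenesis factors were below 0 in 38 of 45 (-0.29, and -0.08 with the other input), with glycolysis genes at -0.26 (-0.30), DNA replication genes at -0.24 (-0.01), hnRNP proteins at -0.23 (-0.05), RGG-motif proteins at -0.21 (-0.18), Sm and LSm proteins at -0.20 (0.06) and SR splicing factors at -0.19 (-0.12). Of these calls by label, snoRNA host RNAs were kept in 4 of 8 settings, Sm and LSm proteins in 5, and aminoacyl-tRNA synthetases, hnRNP proteins and SR splicing factors in 7. Adjustment for GC content and length left hnRNP proteins at -0.12 and Sm and LSm proteins at -0.05, and the lowess trend left the latter at -0.12 and RGG-motif proteins at -0.14. With the other input only mitochondrially encoded messages, snoRNA host RNAs, glycolysis genes and RGG-motif proteins of these still stood apart. In all 288 genes were at least 2-fold higher and 84 lower, 99 and 13 of them protein-coding, against 182 and 111, with 33 and 20 protein-coding, for the other input. By label, small nucleolar RNA genes made up 110 of the 288. The share of higher genes was 77.4%, and 57.9% after adjustment for GC content and length.

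For the PRMT4 inhibitor label the lowest efficiencies were those of HMOX1 (-3.10, and -0.09 with the other input), the unnamed ENSG00000144785 (-2.79 and -0.17), HSPA1B (-1.70 and -0.36), ENSG00000167774 (-1.61 and -0.85), POLG (-1.57 and -1.07) and CBS (-1.57 and -0.60). The highest were AL035425.2 (1.79 and -0.62), the adaptor subunit AP3S1 (1.43 and 0.15), ZNG1E (1.17 and 0.95), the kinetochore protein SPC25 (1.14 and 0.25), H1-3 (1.08 and 0.07) and SUB1 (1.01 and 0.10). Integrated stress response genes were below 0 in 21 of 22 (-0.62), but with the other input 11 were above and 11 below. Genes induced by p53 were below 0 in 17 of 20 (-0.56, and 0.01 with the other input) and ER chaperones in 15 of 19 (-0.37 and -0.11). Aminoacyl-tRNA synthetases had a median of -0.24 (0.00 with the other input), which lay at 0.13 without centring and 0.07 after rescaling. DNA replication genes were above 0 in 35 of 46 (0.26, and -0.01 with the other input), Sm and LSm proteins in 17 of 23 (0.25 and 0.02), KRAB zinc finger genes in 31 of 36 (0.28 and 0.07), ribosome biogenesis factors in 34 of 45 (0.20 and -0.01) and mitochondrial ribosomal proteins in 58 of 74 (0.19 and 0.06), with polyamine metabolism genes at 0.31 (0.05). Nuclear non-coding RNAs (-0.46 and -0.22), small structured RNAs (-0.40 and -0.24) and other oligopyrimidine messages (-0.10 and -0.06) stood apart below with either input, although the last lay at 0.28 without centring and 0.21 after rescaling. No other list of these stood apart with the other input. By label, polyamine metabolism genes were kept in 4 of 8 settings, other oligopyrimidine messages in 5 and ribosome biogenesis factors in 7. Here 73 genes were at least 2-fold higher and 193 lower, 18 and 64 of them protein-coding, against 57 and 80, with 11 and 8 protein-coding, for the other input. The share of higher genes was 27.4% with centring, 79.2% without, 82.4% after rescaling and 63.5% (502 against 289) with no filter. Without centring every list median by label was higher by 0.37, which left integrated stress response genes at -0.25, p53-induced genes at -0.19, ER chaperones at 0.00, nuclear non-coding RNAs at -0.09 and small structured RNAs at -0.03. After rescaling the first 4 of these lay at -0.31, -0.25, -0.07 and -0.16, and KRAB zinc finger genes, DNA replication genes, Sm and LSm proteins, ribosome biogenesis factors, mitochondrial ribosomal proteins and polyamine metabolism genes at 0.61, 0.57, 0.56, 0.51, 0.49 and 0.62. The lowess trend gave DNA replication genes 0.17, Sm and LSm proteins 0.15, mitochondrial ribosomal proteins 0.11, polyamine metabolism genes 0.19 and other oligopyrimidine messages -0.20. Adjustment for GC content and length gave KRAB zinc finger genes 0.14, small structured RNAs -0.23 and other oligopyrimidine messages -0.20.

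Between the inhibitors, 632 genes had a translation efficiency at least 2-fold higher under the PRMT1 inhibitor label and 253 at least 2-fold lower. Of these, 377 and 168 were protein-coding. With inputs exchanged the totals became 225 and 94, with 67 and 18 protein-coding. The balance by label rests on centring, which moved this ratio by 0.35: without it 368 genes were higher and 869 lower, after rescaling 271 and 685, and with no filter on low values 790 and 1136. By label HMOX1, ENSG00000255339, FKBP10 and ENSG00000144785 were the highest of the candidates, and RPS26, CA2, H1-3 and MIX23 the lowest, an order that rests on the labels. With inputs exchanged, the ratio between the inhibitors turned for 6 of these 8, to -0.11 for HMOX1, -1.73 for ENSG00000255339, -2.97 for ENSG00000144785, 0.62 for RPS26, 0.21 for H1-3 and 0.12 for MIX23, and was 0.57 for FKBP10 and -0.12 for CA2. The efficiency ratios of the inhibitors to DMSO had a Pearson correlation of -0.01 and a Spearman correlation of -0.17, where simulated unchanged libraries gave 0.50, with covariances of -0.0023 and 0.27. By label the inhibitors shared 23 of the genes at least 2-fold higher (2.33 for independent lists, 36.1 for simulated lists of the same sizes) and 28 of those lower (1.79 and 39.4). With inputs exchanged they shared 26 (1.15 and 28.6) and 26 (0.98 and 35.1). Over protein-coding genes the standard deviation of the efficiency ratio was 0.354 and 0.365 by label, and 0.328 and 0.243 with the input of the other label. With the other input, 9 lists stood apart for the footprints labelled PRMT1 inhibitor and 5 for those labelled PRMT4 inhibitor, against 13 and 13 by label. Of these, 7 stood apart with the other input alone. For the footprints labelled PRMT1 inhibitor they were KRAB zinc finger genes, above 0 in 30 of 36 (0.17), nuclear oxidative phosphorylation subunits, above 0 in 48 of 75 (0.09), cytoskeleton genes, below 0 in 23 of 27 (-0.23), immediate early genes, below 0 in 12 of 15 (-0.21), and histones, below 0 in 29 of 42 (-0.12). For those labelled PRMT4 inhibitor they were heat shock proteins, below 0 in 18 of 28 (-0.08), and mitosis genes, below 0 in 28 of 45 (-0.06).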

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

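The results in this part were picked because the inhibitors differed in direction: relative to DMSO, the library of one label was higher and that of the other lower, with both list medians apart from random lists, or, for HMOX1, both ratios past 2-fold. None of these differences was tested, since each group had 1 library. For lists, the difference is the median over members of the direct ratio of the inhibitor libraries, so it need not equal the gap between the medians. Integrated stress response genes differed by -0.57 between the inhibitors in input (-0.22 for the PRMT1 and 0.40 for the PRMT4 inhibitor label) and by 0.49 in footprints (0.24 and -0.22). In translation efficiency the difference was 1.12 for these genes (0.42 and -0.62), 0.81 for p53-induced genes (0.30 and -0.56), 0.58 for ER chaperones (0.26 and -0.37) and 0.42 for aminoacyl-tRNA synthetases (0.20 and -0.24). It was -0.51 for DNA replication genes (-0.24 and 0.26), -0.48 for ribosome biogenesis factors (-0.29 and 0.20) and -0.37 for Sm and LSm proteins (-0.20 and 0.25). HMOX1 differed by 5.91 (2.82 and -3.10). With the input of the other label none of these lists stood apart in translation efficiency: the medians were -0.11 for the PRMT1 label and near 0 (11 of 22 members on either side) for the PRMT4 label in integrated stress response genes, -0.11 and 0.01 in p53-induced genes, 0.08 and -0.11 in ER chaperones, 0.09 and 0.00 in aminoacyl-tRNA synthetases, -0.01 and -0.01 in DNA replication genes, -0.08 and -0.01 in ribosome biogenesis factors, and 0.06 and 0.02 in Sm and LSm proteins. HMOX1 was then at -0.20 and -0.09. By label but without centring, aminoacyl-tRNA synthetases were above 0 under both labels in translation efficiency (0.22 and 0.13), and ER chaperones lay at 0.28 and -0.0008. The remaining lists kept opposite signs in translation efficiency on that scale.

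The tests of crossed labels and of footprints moving against the mRNA were chosen only after the crossed correlations had been seen. An account that stays open is that the labels of the 2 inhibitors were crossed in one assay, at the bench, in the labels or in the column names. Its test used genes outside the correlations that raised it, 69 long intergenic non-coding RNAs on none of the lists. For these genes the ratio of the inhibitor libraries to each other correlated between input and footprints at r = -0.39 (95% interval across genes -0.57 to -0.17). They come from the same libraries, so another cause common to a whole library could give a negative r too. The interval treats genes as independent, which they are not. GC content and length bias was not a sufficient account, since r was -0.40 after adjustment, and neither was noise of genes with low values, with r at -0.42 at a mean TPM of at least 50. Footprints moving against the mRNA under the same inhibitor were predicted to give a negative correlation within a label, and the smaller one was 0.204. Both ratios of a label are taken against DMSO, so a trait common to the DMSO input and footprint libraries would raise that correlation. The test therefore cannot exclude such movement. Compensation limited to the difference between the inhibitors also stays possible. If labels were crossed, the data cannot tell in which assay, so every effect here is tied to a label and the translation efficiencies by label may be artefacts of the pairing.

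For small nucleolar RNA in the footprints labelled PRMT1 inhibitor, both tests were chosen after the result was seen. Carry-over of nuclear RNA that no ribosome protected could not be settled. The long nuclear RNAs had a median at percentile 99.6 of random lists in that library, but they also stood apart above in both inputs (0.28 and 0.35), and their translation efficiency lay only at percentile 78.8 by label (0.12) and 93.1 with the other input. More of these RNAs in the cells could not be excluded either: against 2.04 in these footprints, the median input ratio was 0.33 under the same label (14 of 156 genes at least 2-fold higher) and 0.96 under the PRMT4 inhibitor label. A first version of that test used summed TPM, which a single gene, SNORD3A, dominated in input, and was replaced.

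For HMOX1 and FTL, higher in both inhibitor libraries of both assays, the prediction was written before its test was run but after these genes had been seen. A general rise of NRF2 target genes could not be settled: the list lay at percentile 23.59 in the input labelled PRMT1 inhibitor and at 95.6 in that labelled PRMT4 inhibitor. NQO1, another target, had ratios from 0.76 to 0.92 in the 4 libraries, and GCLM from 0.36 to 1.33, both named after their values were seen. HMOX1 also answers to heme and other stress, and a property of the single DMSO library of each assay would raise both inhibitors alike.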

How the results depend on the processing

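Among genes picked by size from all candidates, no ratio behind the pick changed direction under the pseudocounts, the stricter filter, no centring or the lowess trend. These settings could hardly turn a pick. The stricter filter is the threshold that candidates had already passed, so it only moved the centre. A pseudocount cannot turn the ratio of 2 libraries before centring. The picks were the most extreme ratios, so shifts of the centre had little room to turn them. Members picked within lists were not rerun one by one. With the inputs exchanged, translation efficiency changed sign for HMOX1, ENSG00000255339 and RPS26 under the PRMT1 label and for AL035425.2 under the PRMT4 label, and between the inhibitors for HMOX1, ENSG00000255339, ENSG00000144785, RPS26, H1-3 and MIX23. Of 94 calls of a list as apart, 69 stayed on the same side of random lists in every setting run for them (6 to 8) and 25, marked in the report, were lost in at least 1. No centring, which is among the settings counted, moves a list and its random lists alike and could not lose a call. Exchanged inputs, rescaling and the adjustment for GC content and length are not among those settings. With exchanged inputs 7 of the 26 calls in translation efficiency stood and 19 were lost. Among those that stood, nuclear non-coding RNAs and small structured RNAs are not messages, so their ratios say nothing of translation. Mitochondrially encoded messages rest on low footprint values. The others were snoRNA host RNAs, glycolysis genes, RGG-motif proteins and other oligopyrimidine messages. Totals of genes past 2-fold are given in the order input, footprints and translation efficiency, PRMT1 label before PRMT4 label: 74, 221, 346, 81, 372 and 266 in the settings used. More genes were tested at a mean TPM of at least 1 (120, 335, 552, 178, 657 and 508) and with no filter (166, 424, 644, 250, 903 and 791). Fewer were tested at a mean TPM of at least 20, which gave 117 for input under the PRMT4 label, 159 and 33 for footprints, and 167 and 106 for translation efficiency, and with protein-coding genes alone (4, 38, 118, 16, 116 and 85). A pseudocount of 5, which shrinks ratios of low values, gave 42, 113, 193, 38, 202 and 136, and one of 0.1 gave 119 for input under the PRMT1 label and 141 for footprints under the PRMT4 label. Without centring, the total for translation efficiency under the PRMT4 label was 424, since the median of 0.37 was left in. The median of aminoacyl-tRNA synthetases there reversed to 0.13 for the same reason, while the list still stood apart below random lists. Rescaling without small and mitochondrial RNA gave 34, 137, 171, 42 and 218 for all but the last. Adjustment for GC content and length gave 44 and 144 for input, and exchanging the inputs gave 137 for translation efficiency under the PRMT4 label. The Spearman correlation of the inhibitors in translation efficiency was -0.17, against a Pearson value of -0.01. For these last 3 settings and the rescaling the cause was not tested. Centring on a lowess trend moved no total by over 1.5 times. The share of higher genes moved with the scale and with the filter, which also moves the centre, as given beside the counts. Protein-coding genes alone gave shares of 50.0%, 68.4%, 81.4%, 43.8%, 88.8% and 18.8%, and inputs exchanged gave 62.1% and 41.6% for translation efficiency. No paired analysis was possible because each group had 1 library, and leaving out a library was not possible for the same reason. Depth is unknown from TPM, so its limits could not be measured.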

Other observations

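In DMSO, footprints were set against input to compare the 2 assays without an inhibitor, centred like the other ratios. Cytosolic ribosomal proteins had a median log2 ratio of 0.50 against 0.95 for random lists of like expression, and mitochondrially encoded messages, which the ribosomes of the mitochondrion translate, one of -2.66. Nuclear non-coding RNAs were at -1.70, small structured RNAs at -0.44, snoRNA host RNAs at -0.25, ribosome biogenesis factors at -0.16 and aminoacyl-tRNA synthetases at -0.03, all apart below. Above stood hnRNP proteins (1.08), KRAB zinc finger genes (0.44, against -0.35 for random lists), interferon-stimulated genes (0.53) and immediate early genes (0.47). How the input libraries were prepared is not given, so these values may mix ribosome loading of messages with the preparation of each library. Nuclear non-coding and small structured RNAs are not messages, so their ratios do not describe loading.

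GC content followed the input ratios with opposite signs, with a Spearman correlation of -0.37 for the PRMT1 inhibitor label and 0.32 for the PRMT4 inhibitor label over protein-coding genes, and of -0.01 and -0.12 for the footprints. The largest gene held 19.7%, 20.3% and 24.5% of TPM in the inputs of DMSO, the PRMT1 label and the PRMT4 label, and the 10 largest held 43.8%, 49.8% and 57.1%.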
